A study of Mus musculus with 6 samples.

How the data were processed

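Knee articular cartilage of mice was profiled by RNA sequencing in 6 samples, 3 labelled wild type (WT 1 to 3) and 3 labelled adseverin knockout (cKO 1 to 3), and groups and numbers were taken from the sample titles and genotype labels. Per the labels' protocols, tissue was disrupted in a bead mill, total RNA was column-purified, and full-length cDNA libraries were made with a kit for very low RNA input. The Cre driver and the deleted exons are not given in the sources used here.

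The deposited count table holds whole read counts per Ensembl gene, not normalized, for 55401 genes, and the main tests were run on it. The submitters' processing notes name FastQC 0.11.9, HISAT2 2.2.1, featureCounts 2.0.1, R 4.0.5, DESeq2 1.30.1 and the build GRCm38, without settings; the annotation release, strand setting and treatment of multi-mapping reads are not given in the sources used here. A second deposited table holds a normalized signal for 23239 genes, which equals the deposited counts divided by one median-of-ratios size factor per library (largest relative gap 4.00e-11) for genes with at least 6 reads in total. Whole reads were recovered from it for 100% of values above 0, within 0.001 of a read, and 0 of them differed from the count table. Symbols were found for 55141 gene identifiers, and coordinates come from a GRCm38 annotation.

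Read totals ran from 22664828 to 31014996 per library. Libraries of a group were compared with each other over genes with at least 50 reads, and chi-square per degree of freedom was 31.4 to 36.5 over 6 pairs, so none was counted as a duplicate. Genes were filtered with filterByExpr at its defaults, leaving 16260, normalised with TMM and tested with edgeR 4.0.16 in R 4.3.3 by glmQLFit and glmQLFTest with group as the only term and 4 residual degrees of freedom. Significance was a Benjamini-Hochberg adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. An exact permutation test of 3 against 3 cannot go below 0.1, so none was used. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, over the 37 of 39 lists that had at least 5 tested members. There were 25 pathway lists, 13 cell type lists and 1 list of sex-linked genes; the lists, the main tests and the naming rule were chosen before the data were examined.

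The genes named are Scin and its family, up to 12 genes per direction past the threshold with a mean of at least 2 CPM, no overlap between groups and no predicted-gene symbol, and, where fewer than 10 passed in a direction, genes with the smallest unadjusted p up to 10. To these were added up to 4 members of each list past the threshold, or otherwise the 2 with the smallest p, the 2 most abundant members of each cell type list, and Col2a1, Acan, Prg4, Col10a1, Mmp13 and Sox9. Some genes that the rule takes are not reported here. Genes whose values did not overlap between the groups numbered 2001, 12.3% of those tested against 10% by chance.

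Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, limma-trend on log2 of the normalized signal plus 1, RLE and upper-quartile factors, library sizes alone, no filter, a filter of at least 1 CPM in 3 libraries, robust dispersion, the replicate number as a block, leaving out each library and, for lists, camera on ranks. Chosen after the data were seen were DESeq2 on the genes of the edgeR filter, edgeR on the recovered reads, leaving out WT 2 and cKO 3 together, leaving Scin out of the lists, and camera on z scores of the edgeR test with and without a trend over length and GC content removed. DESeq2 gave no adjusted p for 9967 genes. The scripts were tested on 10 simulated sets of counts per gene drawn from the real means, library sizes and dispersions. In each, 200 of 16260 genes were changed. Camera found 10 of 10 lists of 30 genes shifted by 0.3 on the log2 scale, and 0 of 200 unshifted lists passed. The simulated genes varied independently of each other, so this does not give the rate of false list calls in the real libraries. There, groupings other than the genotype put 4 to 15 lists past the threshold. Each of those groupings keeps 2 libraries of 1 genotype on each side. Part of a genotype difference stays in it, so these counts are not that rate either.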

Results

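RNA was sequenced from knee articular cartilage of 10-week-old mice in 2 groups of 3 libraries, one labelled wild type (WT) and one labelled adseverin knockout (cKO). Adseverin, encoded by Scin, is an actin-severing and actin-capping protein of the gelsolin family. Mice of both groups had received tamoxifen at 1.5 mg per 10 g body weight daily for 5 days from 8 weeks of age. The read totals per library were 27576134, 23018642 and 26420506 in WT and 22664828, 31014996 and 23605217 in cKO. The labels number the samples but do not say whether each came from a separate mouse, so p-values measure the spread between these samples, which may be partly technical. All values below are CPM (read counts scaled to library size, TMM-normalised), given as mean ± SD with n = 3 per group, and log2 fold changes are cKO minus WT ± SE.

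The comparison asked which transcripts differed in cartilage after adseverin deletion. Scin (ENSMUSG00000002565, GRCm38 chromosome 12, 40059769 to 40134228) was the gene that fell. It measured 186, 185 and 219 CPM in the WT libraries and 39.1, 29.9 and 29.4 CPM in the cKO libraries, so each library matched its label. The log2 fold change was -2.59 ± 0.14, which left 16.6% of the WT level (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.59e-04). Counts cover the whole gene, and the deleted part is not given in the sources used here. The other measured gelsolin family genes did not pass the threshold. Gsn (gelsolin) stood at 12963 ± 1758 CPM in WT and 13547 ± 822 CPM in cKO, Capg at 335 ± 17.9 CPM in WT and 304 ± 6.63 CPM in cKO and Vill at 122 ± 5.2 CPM in WT and 128 ± 14.2 CPM in cKO. The log2 fold changes of Flii, Svil and Avil were -0.01 ± 0.11, -0.07 ± 0.20 and 0.77 ± 0.48. As a list the family lay lower (camera adjusted p = 3.81e-06; adjusted p = 0.171 with an estimated correlation), and with Scin left out of it, a test chosen after the data were seen, the direction turned upward at an adjusted p of 0.854. With all members the list did not pass on ranks (adjusted p = 0.804) or on z scores of the edgeR test (adjusted p = 0.118). Its median of -0.01 ranged from -0.098 to 0.028 with single libraries left out.

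**Figure D1:**
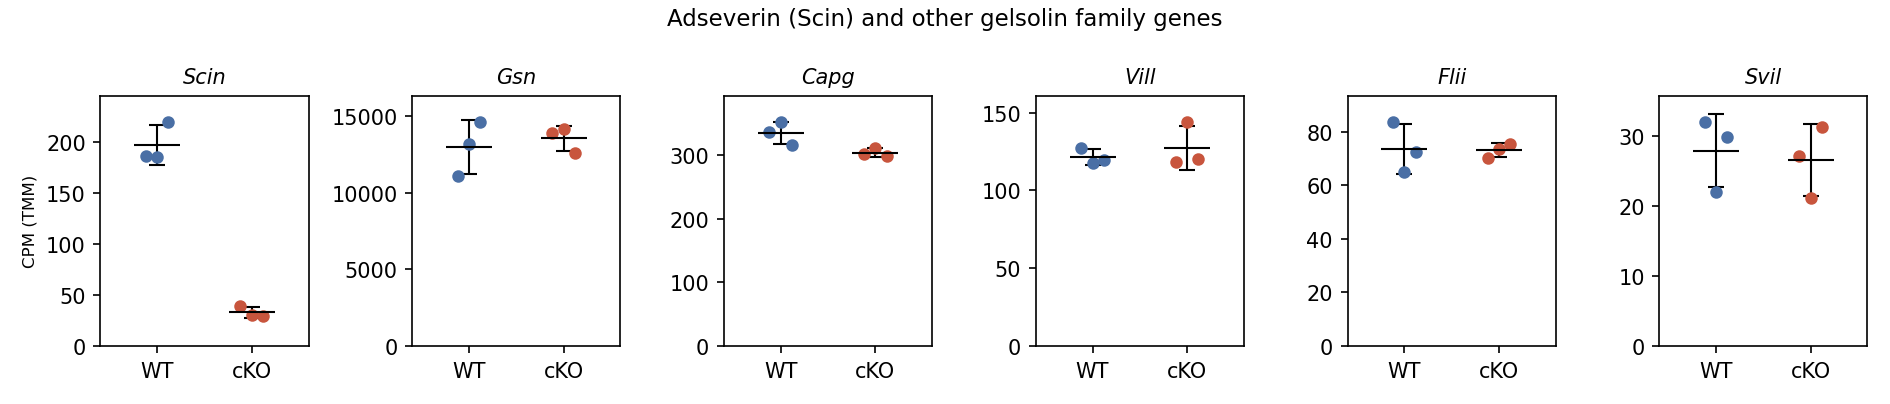
CPM (TMM-normalised, vertical axis from 0) of Scin and 5 other gelsolin family genes in 3 WT and 3 cKO libraries; each point is a library and the bar and whiskers give the mean and SD. Scin lay between 29.4 and 39.1 CPM in cKO against 185 to 219 CPM in WT.

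Of 16260 genes tested, Scin was the 1 gene past an adjusted p of 0.05, with 0 higher and 1 lower in cKO. At an unadjusted p under 0.05 there were 1057 genes, 575 higher and 482 lower, where chance alone would give 813. DESeq2, the tool named in the submitters' processing notes, called 82 genes on the same counts, 40 higher and 42 lower. In counts simulated from these libraries, 27% of the DESeq2 calls and 7.96% of the edgeR calls were genes that had not been changed, and edgeR recovered 12.1% of genes changed 1.5-fold, 42.2% of those changed 2-fold and 67.4% of those changed 4-fold.

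The genes with the smallest p-values after Scin are given as values, since none passed the threshold in edgeR. On the higher side, Trim10, a TRIM family gene, measured 9.65 ± 2.56 CPM in WT and 30.5 ± 2.35 CPM in cKO, and Hhip, a Hedgehog-binding antagonist that is itself a Hedgehog target, measured 136 ± 3.97 CPM in WT and 199 ± 6.65 CPM in cKO. Both had an edgeR adjusted p of 0.268. Chrdl1, a BMP antagonist, stood at 38.2 ± 1.83 CPM in WT and 64.6 ± 6.26 CPM in cKO, and Zdhhc23, a palmitoyltransferase, at 27.6 ± 3.66 CPM in WT and 52.5 ± 3.06 CPM in cKO. Kctd4 and Plcl1 had log2 fold changes of 2.11 ± 0.32 and 2.83 ± 0.45. Slc25a37 (mitoferrin), Hemgn and Rhag, which are erythroid genes, had 0.69 ± 0.11, 2.11 ± 0.35 and 2.25 ± 0.44. Trim10 ranked the 6 libraries in the same order as Hemgn, a comparison made after the values were seen. Whether the rise of Trim10 belongs with that of the erythroid genes was not tested. On the lower side, Tm4sf1 measured 139 ± 8.49 CPM in WT and 84.1 ± 10.1 CPM in cKO, and H2-Ab1, an MHC class II chain, measured 226 ± 26.4 CPM in WT and 141 ± 6.29 CPM in cKO. Its partner chain H2-Aa and the leukocyte phosphatase Ptprc (CD45) had log2 fold changes of -0.59 ± 0.12 and -0.68 ± 0.12. Mcm6, a subunit of the replicative helicase, was at 145 ± 56.1 CPM in WT and 47.1 ± 8.96 CPM in cKO, with WT 2 at 209 CPM. The other subunit genes Mcm2, Mcm3, Mcm4, Mcm5 and Mcm7, added after their values were seen, did not lie lower. They had log2 fold changes of 0.47 ± 0.17, 0.03 ± 0.20, 0.17 ± 0.16, 0.10 ± 0.22 and 0.01 ± 0.14. Socs3, a feedback inhibitor of cytokine signalling, was at 58.5 ± 5.29 CPM in WT and 24 ± 9.46 CPM in cKO. Pfkfb3, Gpt2 and Lamb1 had log2 fold changes of -0.55 ± 0.10, -0.63 ± 0.12 and -1.10 ± 0.22. Lamb1 lies on chromosome 12 within 10 Mb of Scin. With DESeq2, H2-Ab1, Hhip and Trim10 reached adjusted p-values of 3.67e-06, 2.60e-06 and 4.62e-09.

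Gene lists fixed before the data were examined were compared with the remaining genes. With camera at a preset inter-gene correlation of 0.01, 22 of 37 tested lists passed an adjusted p of 0.05, 7 higher and 15 lower in cKO. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.171, and fry, which asks whether the genes of a list move on balance one way, passed 1 list, the gelsolin family. That list holds Scin itself, and 3 of its 7 measured members were above 0. Fry was not repeated without Scin, so this pass says little about the rest of the family. Adjusted over the union of 776 list members, 2 genes passed, Scin and Hhip (adjusted p = 0.0248 for Hhip).

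**Figure D2:**
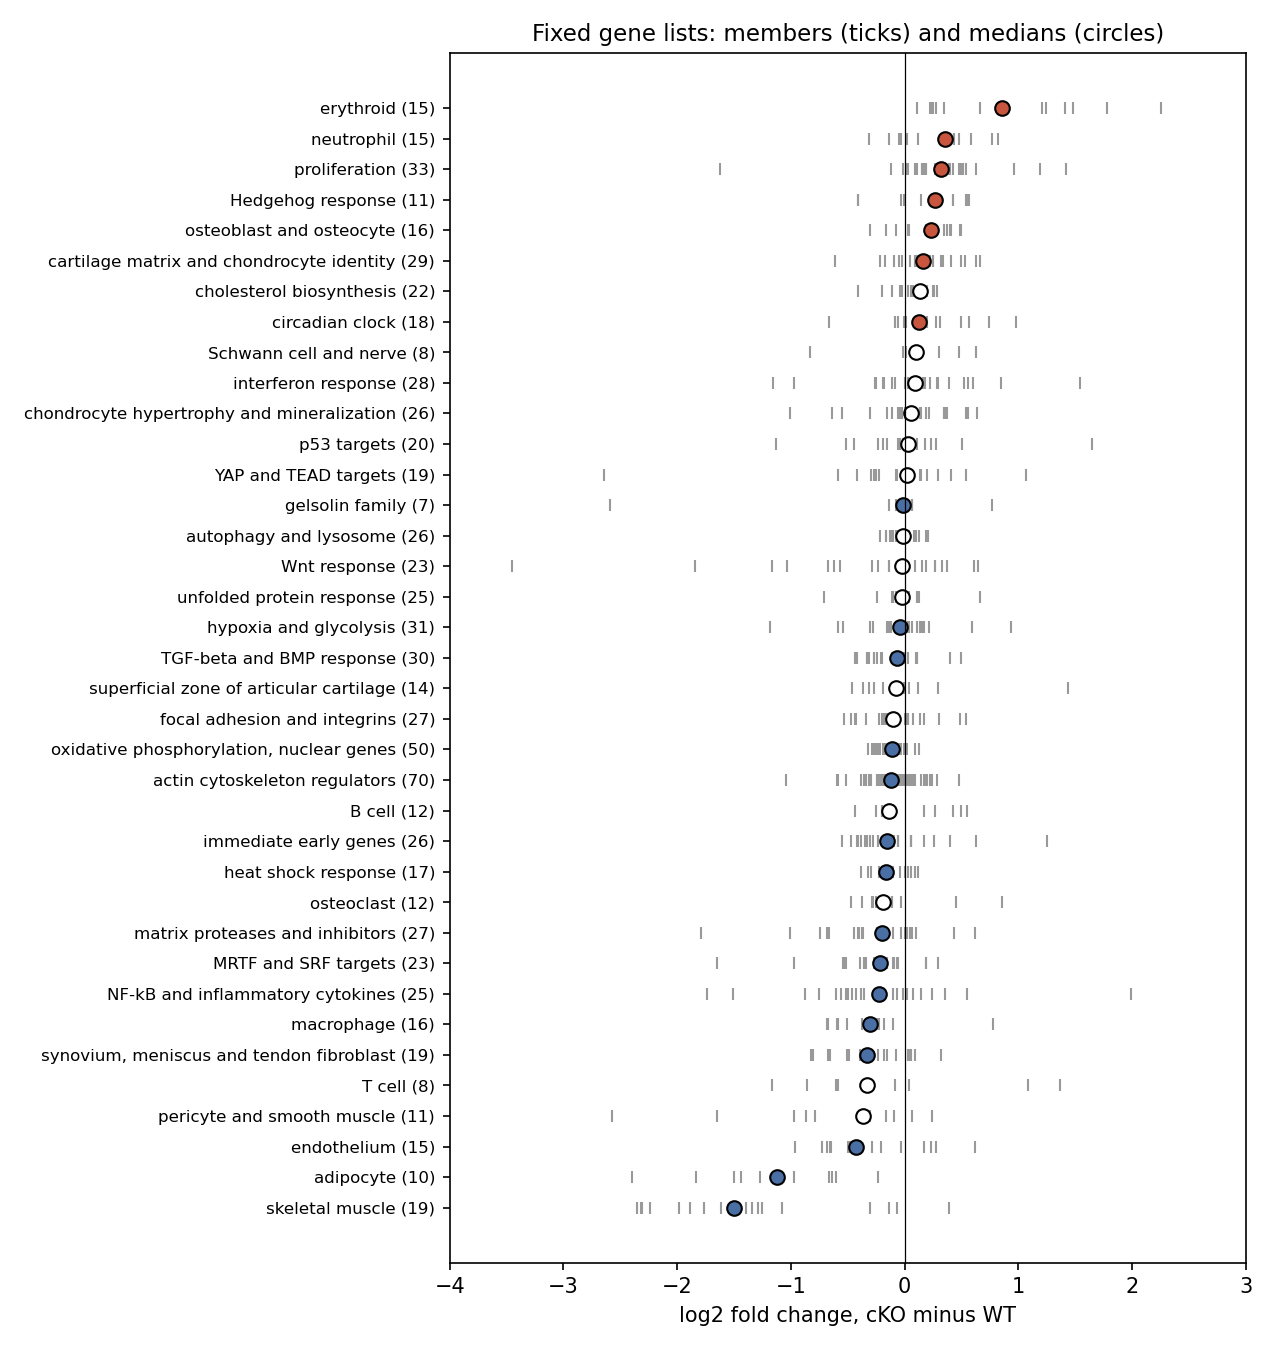
Log2 fold changes, cKO minus WT (horizontal axis), of the members of the 37 tested lists (ticks, number of measured genes in parentheses) with the list median (circles). Filled circles passed camera at the preset correlation, red higher and blue lower in cKO, and open circles did not; the erythroid median was 0.85 and the skeletal muscle median -1.50.

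Genes of the cartilage matrix and of chondrocyte identity lay higher as a list, while aggrecan lay lower. Of 29 measured members, 23 had a log2 fold change above 0 (median 0.17, camera adjusted p = 1.98e-04; adjusted p = 0.401 with an estimated correlation). The list passed with each single library left out, most weakly without cKO 2 (camera adjusted p = 0.0366, median 0.13). Col2a1, the main collagen of cartilage, was at 14840.5 ± 429 CPM in WT and 17598 ± 2603 CPM in cKO, with cKO 2 at 20596 CPM. Its log2 fold change ranged from 0.12 to 0.31 with single libraries left out. Fgfr3 was at 59.4 ± 5.15 CPM in WT and 91.6 ± 23.6 CPM in cKO and Sox9, the chondrocyte transcription factor, at 1621 ± 207 CPM in WT and 1893 ± 106 CPM in cKO. Acan, the large aggregating proteoglycan, was at 1345 ± 85.9 CPM in WT and 882 ± 152 CPM in cKO (log2 fold change -0.61 ± 0.13, edgeR adjusted p = 0.535), and it was the 1 member to pass when adjusted over the list alone. In the same comparison markers of fibroblasts (median -0.33), macrophages (median -0.31) and adipocytes (median -1.12) lay lower and those of osteoblasts and osteocytes (median 0.24) higher, at adjusted p-values of 0.316, 0.335, 0.401 and 0.560 with an estimated correlation. Those medians were -0.18 for fibroblasts and -0.59 for adipocytes without WT 2, -0.18 for macrophages without WT 1 and -0.20 without cKO 1, and 0.37 for osteoblasts without cKO 2 and 0.033 without cKO 3; adipocytes did not pass without WT 2, nor osteoblasts without WT 3 or cKO 3. The superficial zone list did not pass (adjusted p = 0.488), with Clu, the 1 member past the threshold adjusted over the list alone, at -0.46 ± 0.11 on the log2 scale and Abi3bp at 0.29 ± 0.08. Prg4, which encodes lubricin, was at 5255 ± 349.6 CPM in WT and 5222 ± 696 CPM in cKO. The hypertrophy and mineralization list did not pass either (adjusted p = 0.0796), although it passed as higher without WT 3 (adjusted p = 0.0242), and Ihh, Mef2c and Foxa2 passed when adjusted over the list alone. Ihh was at 111 ± 18.7 CPM in WT and 162 ± 17.2 CPM in cKO and Mef2c at 497 ± 35.4 CPM in WT and 631 ± 43.6 CPM in cKO, whereas Col10a1 was at 3318 ± 349 CPM in WT and 3367 ± 401 CPM in cKO.

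Hedgehog response genes lay higher as a list (7 of 11 above 0, median 0.26, camera adjusted p = 1.98e-04, and adjusted p = 0.316 with an estimated correlation). The median was 0.15 without WT 1. Osteoblast and osteocyte markers lay higher (median 0.24, camera adjusted p = 0.00296) and fibroblast markers lower (median -0.33, camera adjusted p = 6.54e-04) in the same comparison, at adjusted p-values of 0.560 and 0.316 with an estimated correlation. The osteoblast list did not pass without WT 3 (median 0.17) or cKO 3 (median 0.033; 0.37 without cKO 2), and the fibroblast median was -0.18 without WT 2. Adjusted over the list alone, Hhip, Ptch1 and Ihh passed as higher and Gas1 as lower. Ptch1, the Hedgehog receptor and a target of the pathway, was at 107 ± 10.3 CPM in WT and 143 ± 9.74 CPM in cKO. Gli1 and Gli3 had log2 fold changes of 0.57 ± 0.22 and 0.42 ± 0.17, and Gas1, a Hedgehog co-receptor, had -0.41 ± 0.11. Gli2 and Smo had 0.15 ± 0.17 and -0.03 ± 0.09. Gli1, Gli2, Gli3, Smo and Gas1 fell outside the naming rule and were chosen after their values were seen.

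Matrix proteases and their inhibitors lay lower as a list (median -0.20, 19 of 27 below 0, camera adjusted p = 1.17e-04; adjusted p = 0.194 with an estimated correlation). Serpina3n was at 62.2 ± 6.04 CPM in WT and 38.9 ± 10.7 CPM in cKO and the aggrecanase Adamts4 at 9.77 ± 2.77 CPM in WT and 2.81 ± 1.74 CPM in cKO. Mmp13, a collagenase, was at 1013 ± 533 CPM in WT and 503 ± 197 CPM in cKO, with a log2 fold change of -1.01 ± 0.40. Ctsk and Mmp9 of this list are also osteoclast markers, a list that did not pass (adjusted p = 0.655). Markers of fibroblasts (median -0.33, adjusted p = 6.54e-04) and macrophages (median -0.31, adjusted p = 1.98e-04) lay lower in the same comparison, with adjusted p-values of 0.316 and 0.335 with an estimated correlation.

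Actin-related lists lay lower. Of 70 actin cytoskeleton regulators, 51 were below 0 (median -0.12, camera adjusted p = 7.02e-05; adjusted p = 0.316 with an estimated correlation), with Fscn1 at -1.05 ± 0.26 and Pxn at -0.52 ± 0.13 on the log2 scale. Of 23 targets of MRTF and SRF, the actin-regulated transcription factors, 20 were below 0 (median -0.22, camera adjusted p = 2.11e-05; adjusted p = 0.201 with an estimated correlation). The MRTF and SRF median was -0.13 without WT 2. Actb, Actg1, Flna, Myh9, Tpm1, Vcl and Zyx are in both lists and lay below 0, so the lists are not independent. Acta2 (log2 fold change -1.65) and Tagln (-0.98), named after their values were seen, are members of the MRTF and SRF list and of the pericyte and smooth muscle list, which did not pass (median -0.37, -0.23 without WT 2). Fibroblast markers lay lower (median -0.33, -0.18 without WT 2; camera adjusted p = 6.54e-04, adjusted p = 0.316 with an estimated correlation). Tagln2, at 109 ± 9.12 CPM in WT and 75.7 ± 9.72 CPM in cKO, passed when adjusted over the MRTF and SRF list alone, and Fhl2 was at -0.54 ± 0.18. YAP and TEAD targets did not pass (adjusted p = 0.588), with a median of 0.02 but a mean of -0.10; F3 and Nt5e were at -0.58 ± 0.18 and -0.30 ± 0.10. Focal adhesion and integrin genes did not pass (adjusted p = 0.254), with Tns2 at 0.31 ± 0.09 and Itga11 at -0.44 ± 0.19, but passed as lower without WT 3 (adjusted p = 0.0387).

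Nuclear genes of oxidative phosphorylation lay lower by a small amount. Of 50 genes 45 were below 0, with a median of -0.11 (camera adjusted p = 3.81e-06; adjusted p = 0.335 with an estimated correlation); Ndufb8 was at 129 ± 3.63 CPM in WT and 108 ± 3.99 CPM in cKO and Atp5g3 at -0.26 ± 0.09 on the log2 scale. The oxidative phosphorylation median was -0.17 without WT 1. In the same comparison markers of fibroblasts, macrophages, adipocytes and endothelium lay lower (medians -0.33, -0.31, -1.12 and -0.43). Their adjusted p-values with an estimated correlation were 0.316, 0.335, 0.401 and 0.561. Erythroid, neutrophil and osteoblast markers lay higher (medians 0.85, 0.36 and 0.24). The 13 mitochondrially encoded genes were listed at 0 in every library. Hypoxia and glycolysis genes lay lower (median -0.04, camera adjusted p = 0.0404; adjusted p = 0.560 with an estimated correlation), and Pfkfb3, Hk2 and Ddit4 passed when adjusted over the list alone, Hk2 being at 29.8 ± 3.77 CPM in WT and 19.9 ± 0.942 CPM in cKO. That list did not pass without WT 3 (adjusted p = 0.451, median -0.012) or without cKO 1 (adjusted p = 0.383, median -0.023), nor on ranks (adjusted p = 0.149) or with a trend over length and GC content removed (adjusted p = 0.0526). Its median was -0.072 without WT 2, -0.068 without cKO 2 and -0.075 without cKO 3. Cholesterol biosynthesis genes did not pass (adjusted p = 0.154), with Sqle at 0.29 ± 0.11 and Hsd17b7 at -0.41 ± 0.17, nor did autophagy and lysosome genes (adjusted p = 0.659), with Ulk2 at 0.20 ± 0.13 and Lamp2 at -0.13 ± 0.09; the cholesterol list passed as higher without WT 3 (adjusted p = 0.0101).

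Of 8 stress and signalling lists, 4 passed as lower and 4 did not pass. NF-kB and cytokine genes had a median of -0.23 (camera adjusted p = 0.00920; adjusted p = 0.316 with an estimated correlation), with Ccl7 at -1.51 ± 0.59 and Icam1 at -0.38 ± 0.15. They did not pass without WT 1 (adjusted p = 0.100, median -0.20), and the median was -0.43 without WT 3 and -0.35 without cKO 3. Ccl7 was at -0.77 without WT 1. Macrophage markers lay lower in the same comparison (median -0.31, camera adjusted p = 1.98e-04; adjusted p = 0.335 with an estimated correlation). Immediate early genes had a median of -0.15 (camera adjusted p = 0.0239; adjusted p = 0.560 with an estimated correlation), with Fosl2 at -0.35 ± 0.12 and Jund at -0.41 ± 0.15. Heat shock genes had a median of -0.17 (camera adjusted p = 0.0110; adjusted p = 0.335 with an estimated correlation), with Hspd1 at 95.6 ± 2.07 CPM in WT and 77.6 ± 3.45 CPM in cKO and Hspa8 at -0.17 ± 0.08. TGF-beta and BMP response genes had a median of -0.07 (camera adjusted p = 0.0423; adjusted p = 0.316 with an estimated correlation), with Id3 at -0.24 ± 0.12 and Tgfbi at -0.33 ± 0.17. The immediate early list did not pass without WT 2 (adjusted p = 0.423, median -0.043), without cKO 2 (adjusted p = 0.203, median -0.089) or without cKO 3 (adjusted p = 0.278, median -0.10), nor with a trend over length and GC content removed (adjusted p = 0.0526), and its direction turned with WT 2 and cKO 3 both left out (adjusted p = 0.954). Its median was -0.25 without WT 1, -0.10 without WT 3 and -0.34 without cKO 1. The heat shock list did not pass without WT 2 (adjusted p = 0.167, median -0.10) or without cKO 3 (adjusted p = 0.0618, median -0.13). The TGF-beta and BMP list did not pass without WT 2 (adjusted p = 0.134, median -0.076), without WT 3 (adjusted p = 0.105, median -0.085), without cKO 2 (adjusted p = 0.0819, median -0.091) or without cKO 3 (adjusted p = 0.193, median -0.077), and its median was -0.11 without WT 1 and -0.10 without cKO 1. The unfolded protein response list did not pass (adjusted p = 0.326), with Hyou1 at -0.71 ± 0.34 and Dnajb9 at -0.25 ± 0.12. Neither did the Wnt list (adjusted p = 0.780), where Dkk1 and Frzb passed as higher and Ccn5 and Sfrp2 as lower when adjusted over the list alone. Dkk1, a Wnt inhibitor, was at 69.5 ± 2.53 CPM in WT and 109 ± 23.1 CPM in cKO, and Ccn5 was at 139.9 ± 49.4 CPM in WT and 68.4 ± 12 CPM in cKO. The p53 list (adjusted p = 0.919; Trp53inp1 -0.51 ± 0.15, Fas 0.51 ± 0.16) and the interferon list (adjusted p = 0.326; Rsad2 0.52 ± 0.19, Oas3 1.54 ± 0.55) did not pass.

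Circadian clock genes lay higher as a list (median 0.13 over 18 genes, camera adjusted p = 0.00221; adjusted p = 0.201 with an estimated correlation), and Arntl and Per3 passed when adjusted over the list alone. Arntl, which encodes the clock activator BMAL1, was at 5.45 ± 1.21 CPM in WT and 10.8 ± 0.326 CPM in cKO, and Per3 was at 123 ± 24.5 CPM in WT and 181 ± 8.41 CPM in cKO. The clock median was 0.075 without WT 1, 0.19 without WT 3 and 0.22 without cKO 1. The labels give no time of day for the harvest. Proliferation genes lay higher (30 of 33 above 0, median 0.32, camera adjusted p = 7.02e-05; adjusted p = 0.560 with an estimated correlation). Ccne1 (cyclin E1) was at 4.04 ± 1.51 CPM in WT and 10.8 ± 1.54 CPM in cKO. Adjusted over the list alone, Ccne1 and Mki67 passed as higher and Mcm6 as lower. The proliferation list did not pass without WT 2 (adjusted p = 0.0799, median 0.14) or without cKO 3 (adjusted p = 0.109, median 0.12), and with both left out its direction turned (adjusted p = 0.761). The erythroid list lay higher in cKO as well (median 0.85 with all libraries, 0.60 without cKO 3 and 0.66 without WT 2).

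Markers of other cell types differed between the libraries. Erythroid genes lay higher in cKO, with all 15 members above 0 (median 0.85, camera adjusted p = 3.00e-15; adjusted p = 0.171 with an estimated correlation) and 8 past the threshold when adjusted over the list alone. Rhag was at 2.68 ± 0.35 CPM in WT and 12.8 ± 8.08 CPM in cKO (log2 fold change 1.62 without cKO 3) and Klf1, the erythroid transcription factor, at 5.21 ± 1.79 CPM in WT and 14.5 ± 5.41 CPM in cKO. The haemoglobins, the most abundant members, differed less, with Hbb-bs at 996 ± 148 CPM in WT and 1173 ± 235 CPM in cKO and Hba-a1 at 727 ± 81.1 CPM in WT and 849.8 ± 213 CPM in cKO. Neutrophil genes lay higher (median 0.36, camera adjusted p = 0.0195; adjusted p = 0.637 with an estimated correlation). Retnlg was at 0.77 ± 0.30, Ly6g at 0.82 ± 0.39, Ngp at 0.40 ± 0.29 and S100a8 at 0.35 ± 0.28. The neutrophil list did not pass without WT 2 (adjusted p = 0.364, median 0.12) or without cKO 3 (adjusted p = 0.509, median -0.011). Without cKO 3 its direction turned, and its median was 0.56 without WT 1. Osteoblast and osteocyte genes lay higher (median 0.24, camera adjusted p = 0.00296; adjusted p = 0.560 with an estimated correlation). Irx5 was at 0.40 ± 0.15, Sp7 at 0.22 ± 0.09 and Ibsp at 24417 ± 1173 CPM in WT and 27838 ± 3045 CPM in cKO. The osteoblast list did not pass without WT 3 (adjusted p = 0.160, median 0.17) or without cKO 3 (adjusted p = 0.540, median 0.033), and its median was 0.37 without cKO 2.

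**Figure D3:**
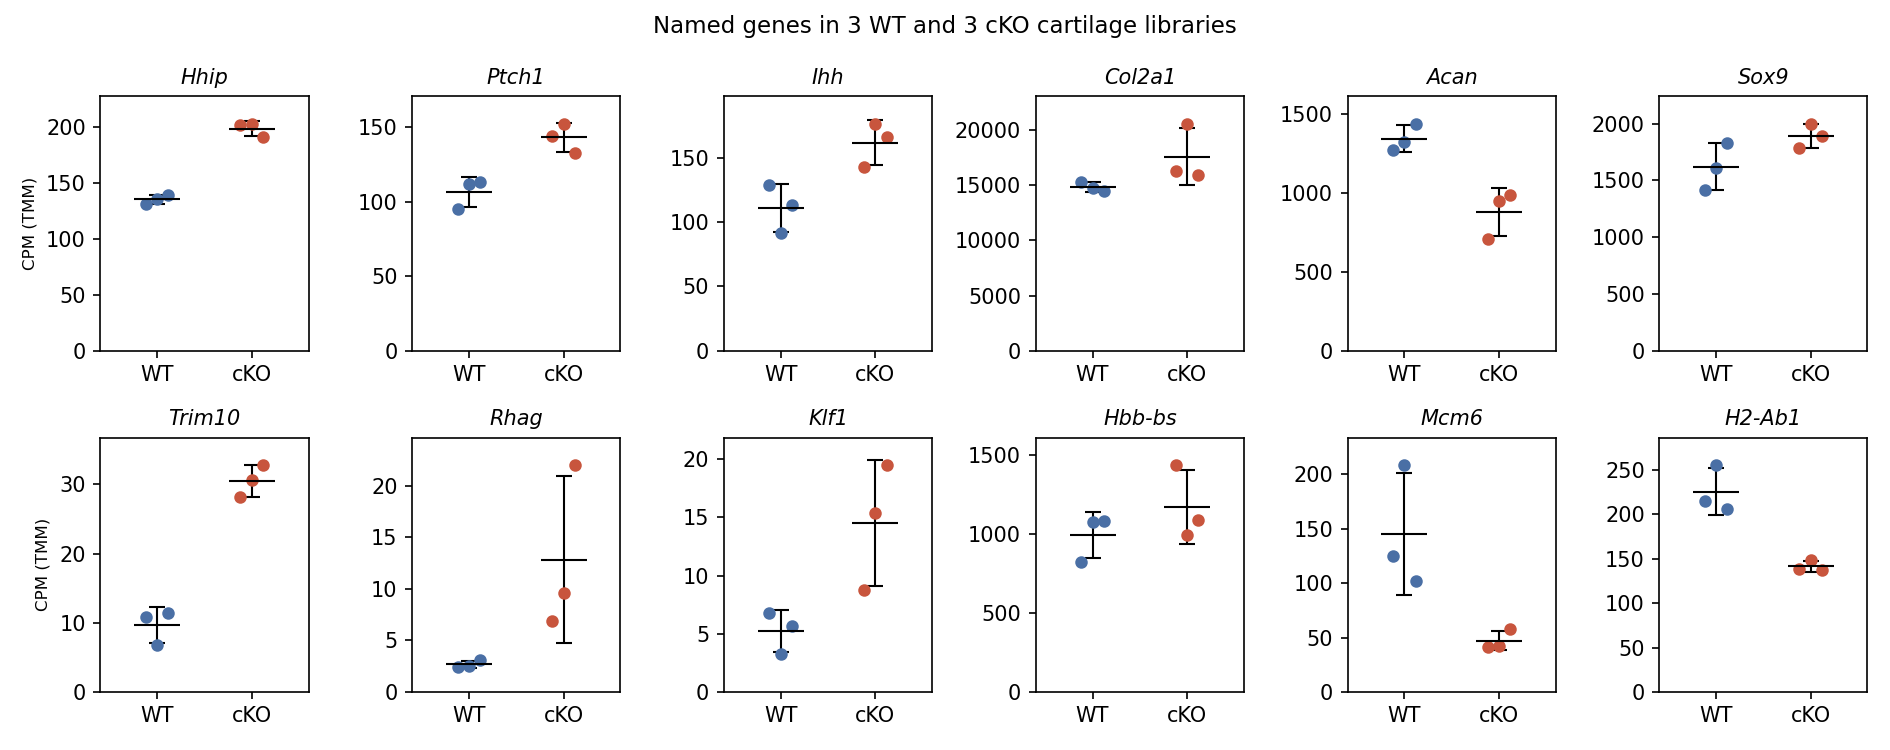
CPM (TMM-normalised, vertical axes from 0) of 12 named genes in 3 WT and 3 cKO libraries; each point is a library and the bar and whiskers give the mean and SD. Hhip lay at 136 CPM in WT and 199 CPM in cKO, and Acan at 1345 and 882 CPM.

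Skeletal muscle genes lay lower (median -1.50, camera adjusted p = 0.04995; adjusted p = 0.681 with an estimated correlation), and this rested on WT 2, where Acta1 was at 762 CPM against 4.73 to 99.2 CPM in the other 5 libraries. Without WT 2 the list turned to higher in cKO (adjusted p = 9.96e-06, median 1.21), and it did not pass without cKO 1 (adjusted p = 0.0944) or cKO 3 (adjusted p = 0.600), with RLE factors (adjusted p = 0.0575) or with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0787). Myl1, Casq1 and Ttn had log2 fold changes of -2.24 ± 1.50, -2.35 ± 0.87 and -1.26 ± 0.74 with all libraries, and 2.04, -0.57 and 0.35 without WT 2. Macrophage genes lay lower (15 of 16 below 0, median -0.31, camera adjusted p = 1.98e-04; adjusted p = 0.335 with an estimated correlation). C1qa was at 26.1 ± 4.57 CPM in WT and 16.3 ± 4.0 CPM in cKO, Trem2 at -0.59 ± 0.29, Lyz2 at -0.27 ± 0.16 and Cd14 at -0.29 ± 0.15. The macrophage median was -0.18 without WT 1 and -0.20 without cKO 1. Fibroblast genes of synovium, meniscus and tendon lay lower (median -0.33, camera adjusted p = 6.54e-04; adjusted p = 0.316 with an estimated correlation). Lum was at 979 ± 71.2 CPM in WT and 689 ± 199 CPM in cKO, Col3a1 at -0.67 ± 0.25, Col1a1 at -0.08 ± 0.23 and Col1a2 at 0.04 ± 0.20. The fibroblast median was -0.18 without WT 2. All 10 adipocyte genes were below 0 (median -1.12, camera adjusted p = 2.15e-04; adjusted p = 0.401 with an estimated correlation). Cfd was at -2.40 ± 0.78 and Fabp4 at -1.27 ± 0.42, but without WT 2 Cfd was at -1.45. The adipocyte list did not pass without WT 2 (adjusted p = 0.134, median -0.59). Endothelial genes lay lower (median -0.43, camera adjusted p = 0.0195; adjusted p = 0.561 with an estimated correlation). Plvap was at -0.69 ± 0.27, Esam at -0.50 ± 0.23 and Eng at -0.04 ± 0.15. The list did not pass without WT 2 (adjusted p = 0.167, median -0.24), without cKO 1 (adjusted p = 0.137, median -0.29) or without cKO 2 (adjusted p = 0.444, median -0.20), and its median was -0.69 without cKO 3. Markers of the remaining types did not pass. The adjusted p was 0.919 for B cells (Ebf1 0.55 ± 0.22, Ighm -0.25 ± 0.16), whose median of -0.14 was opposite in sign to the test, and 0.421 for T cells (Cd3d 1.37 ± 0.76, Cd4 -1.17 ± 0.69, Lck -0.58 ± 0.36, Cd2 0.04 ± 0.42). It was 0.655 for osteoclasts (Car2 0.85 ± 0.21, Nfatc1 -0.21 ± 0.09, Ctsk -0.37 ± 0.30, Mmp9 -0.03 ± 0.34) and 0.0937 for pericytes and smooth muscle (Cspg4 0.24 ± 0.09, Myh11 -2.57 ± 1.31, Rgs5 0.07 ± 0.32). It was 0.254 for Schwann cells and nerve (Egr2 0.62 ± 0.26, Pmp22 0.02 ± 0.07, Ncmap 0.10 ± 0.10). Myh11, at 13.3 CPM in WT 2 against 0.534 and 2.2 CPM in WT 1 and WT 3, had -0.62 without WT 2 and -4.50 without cKO 3, and Cd3d had 2.16 without WT 1. Osteoclast markers passed as lower without WT 2 (adjusted p = 0.00377) and Schwann cell markers as higher without WT 2 (adjusted p = 0.0208). Pericyte and smooth muscle markers passed as lower on ranks (adjusted p = 0.0429), and also without WT 3 (adjusted p = 0.0132) and without cKO 3 (adjusted p = 0.00994). The sex-linked genes had too few measured members for a list test, and the Y-linked genes Uty and Ddx3y were at 0.17 ± 0.24 and -0.04 ± 0.08.

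Some of these values are uncertain because reads may be shared. The strand setting of the counting is not given in the sources used here, and annotated exons of Avil, Flii, Hhip, Slc25a37, Fgfr3, Adamts4, Icam1, Jund, Hspd1, Hspa8, Dnajb9, Ndufb8, Arntl, Casq1, Ttn, Lck, Col3a1, Eng, Prg4, Col10a1, Gli1, Gli3, Gas1 and Mcm7 overlap an exon of another gene. Hba-a1 and Hbb-bs have near-identical copies.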

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

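Tests on DESeq2 with the edgeR filter, on reads recovered from the normalized table, without WT 2 and cKO 3 together, with Scin left out of the lists, and on z scores with or without a length and GC trend removed were chosen after the data were seen. The Scin log2 fold change stayed between -2.73 and -2.50 when each library was left out in turn and passed in each of those fits, but with WT 2 and cKO 3 both left out it was -2.56 with an adjusted p of 0.0536, where 2 libraries per group remained. Splits of the 6 libraries into 3 against 3 number 10, too few for a share under 0.05. The real split called 1 gene against at most 0 in the others, and put 22 lists past the threshold against at most 15; in each case 1 of the 10 splits, the real one, gave a count as large.

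The count of 1 changed gene (0 higher, 1 lower) became 82 (40 higher, 42 lower) with DESeq2, both on all genes and on the genes of the edgeR filter, and 3 (1 higher, 2 lower) with no filter. It became 0, with 0 lower, with WT 2 and cKO 3 both left out, and ranged from 1 to 2, with 1 to 2 lower, when single libraries were left out, the 2 occurring without WT 3, where the other gene was Gm7292; with no filter the others were Trim10 and Mcm6. These 3 were taken after their values were seen. The cause was not tested, except that the simulated false calls of DESeq2 bear on the first. With the replicate number as a block the count was 1 gene and 21 lists, 20 of them among the 22; skeletal muscle (adjusted p = 0.0892) and hypoxia (adjusted p = 0.0594) no longer passed and pericytes (adjusted p = 0.0298) did. The labels do not say whether the numbers pair the samples. After each group's mean was subtracted, the correlations of same-numbered libraries were -0.02, 0.07 and 0.02. Of 6 libraries, 3 correlated best with their own number. These values show little sign of pairing but cannot exclude it, since subtracting the mean of so few libraries ties the values of a group together. The count of list members past the threshold over the union of lists was 2, and became 40 with DESeq2, 41 with DESeq2 on the edgeR filter, 26 with no filter, 1 with the replicate block and 4 with WT 2 and cKO 3 both left out, and 1 to 4 with single libraries left out, 4 without cKO 1 and 1 without cKO 3. The count of 22 lists became 0 with an estimated correlation and 1 with fry. It was 16 to 23 with single libraries left out, 21 on z scores (the gelsolin list no longer passing), 19 on z scores with the length and GC trend removed, which ended 2 more calls, hypoxia and immediate early genes, and 19 with WT 2 and cKO 3 both left out. The test on recovered reads, of which 100% were whole within 0.001 of a read, called 1 gene.

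Of 2395 comparisons of the 120 named genes with an alternative, 2291 kept direction and side of the threshold, 60 newly passed it, 1 no longer did and 43 changed sign, each for a gene that had not passed. With single libraries left out the log2 fold changes that changed sign ranged from -2.56 to 1.96 for Acta1, from -0.13 to 0.29 for Cd2, from -0.082 to 0.075 for Col10a1, from -0.34 to 0.14 for Col1a1, from -0.22 to 0.19 for Col1a2, from -0.096 to 0.0031 for Ddx3y, from -0.10 to 0.062 for Eng, from -0.098 to 0.086 for Flii, from -0.041 to 0.16 for Gsn, from -0.32 to 0.25 for Mmp9, from -2.80 to 2.04 for Myl1, from -0.022 to 0.041 for Pmp22, from -0.11 to 0.079 for Prg4, from -0.16 to 0.43 for Rgs5, from -0.023 to 0.52 for S100a8, from -0.23 to 0.065 for Svil, from -1.68 to 0.35 for Ttn, from -0.085 to 0.34 for Uty and from -0.028 to 0.12 for Vill. With WT 2 and cKO 3 both left out they were 0.55 for Ttn, 2.51 for Acta1, 2.58 for Myl1, -0.12 for Ngp, -0.23 for S100a8, -0.31 for Col1a2, 0.0073 for Eng and -0.049 for Uty. Among the called lists, skeletal muscle turned to higher without WT 2 (adjusted p range 4.31e-06 to 0.600 over single libraries) and neutrophil to lower without cKO 3 (3.94e-06 to 0.509). With WT 2 and cKO 3 both left out the adjusted p of lists that turned was 1.86e-26 for skeletal muscle, 0.00322 for neutrophil, 0.761 for proliferation and 0.954 for immediate early genes. With Scin left out, that of the gelsolin list was 0.854, and that of skeletal muscle, no longer past the threshold, 0.0523. Lists that had not passed turned direction as well. Their adjusted p ranged, over single libraries left out, from 0.117 to 0.975 for superficial zone of articular cartilage, from 0.106 to 0.934 for YAP and TEAD targets, from 0.592 to 0.959 for p53 targets, from 0.448 to 0.967 for autophagy and lysosome, from 0.379 to 0.921 for B cell, from 0.205 to 0.915 for T cell, from 0.00377 to 0.732 for osteoclast and from 0.0208 to 0.959 for Schwann cell and nerve. On other settings it was 0.878 for B cells on ranks, 0.982 for Wnt with the filter of at least 1 CPM and, with WT 2 and cKO 3 both left out, 0.692 for B cells, 0.954 for T cells and 0.954 for YAP and TEAD targets. At read totals of 22664828 to 31014996 per library, the median SE of a log2 fold change was 0.229 over all genes and 0.146 over genes of at least 10 CPM.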

Other observations

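Leaving out each library was planned, and the other tests below, with the patterns they bear on, were chosen after the results were seen. Some genes, chosen after their values were seen, are given as values, as none passed the edgeR threshold. H2-Ab1, H2-Aa and H2-Eb1, which encode MHC class II chains, had log2 fold changes of -0.67 ± 0.10, -0.59 ± 0.12 and -0.79 ± 0.16, and the invariant chain gene Cd74 had -0.61 ± 0.14. H2-DMa, H2-DMb1 and Ciita, of the same pathway, had -0.46 ± 0.23, -0.06 ± 0.14 and -1.46 ± 0.68. Ptprc and Nckap1l, both leukocyte genes, had -0.68 ± 0.12 and -0.69 ± 0.14, and the complement gene C4b was at 271 ± 14.9 CPM in WT and 184 ± 30.1 CPM in cKO. The fixed macrophage markers lay lower in the same comparison (15 of 16 below 0, median -0.31, -0.18 without WT 1 and -0.20 without cKO 1; adjusted p = 0.335 with an estimated correlation). Exons of Ciita, H2-DMa and Cd74 overlap an exon of another gene, and Ciita was at 2.11 ± 1.44 CPM in WT and 0.764 ± 0.175 CPM in cKO.

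Erythroid genes lay higher in cKO (median 0.85), and Car2 of that list is also an osteoclast marker. Bone marrow carried over with the cKO samples would bring its other cells, and the 27 neutrophil and B cell genes together had a median of 0.17 (interquartile range 0.58; the B cell genes alone -0.14), against 1.21 (interquartile range 0.68) for the 11 erythroid genes other than haemoglobins. Whole marrow stays open even so. The pooled 27 genes had a higher level in WT (median 38 CPM against 10.5 CPM). That would hide a small added share only if the WT level came from a source other than marrow, which was not tested. The condition on the WT level was added after the values were seen, and the bound used before it read them as against whole marrow. A higher WT level is not shown for the B cell genes alone. Their 12 genes summed to 240 CPM in WT, mostly from Ighm (79.0 CPM), Ebf1 (68.2 CPM) and Igkc (48.9 CPM). Their log2 fold changes ran from -0.43 to 0.55, too wide a spread to decide. Within each group the summed neutrophil genes ranked the libraries as Klf1 did. They were at 2196, 1236 and 1729 CPM with Klf1 at 6.76, 3.25 and 5.62 CPM in WT 1 to 3. In cKO 1 to 3 they were at 1465, 1879.7 and 3065 CPM with Klf1 at 8.77, 15.3 and 19.5 CPM. Across the groups this ranking did not hold, as cKO 1 was below WT 1 and WT 3 in the neutrophil genes and above both in Klf1. The single library cKO 3 is argued against as the whole cause, since without it the median was 0.60 and the list passed (camera adjusted p = 7.32e-12). A camera pass of this list is limited support. It also passed in some groupings other than the genotype, but each of those keeps 2 libraries of 1 genotype on each side. Part of a genotype difference stays in them, so such passes cannot tell spread between libraries from a true shift. The camera adjusted p of the list was 2.06e-08 for WT 1, WT 2 and cKO 2 against the rest, but 0.839 for WT 1, WT 3 and cKO 3 against the rest. With all libraries the list did not pass with an estimated correlation (adjusted p = 0.171). Erythroid cells without the rest of the marrow may also be the source, as the 4 haemoglobins had a median of 0.24 and a high level in WT (996 CPM for Hbb-bs). Hbb-bs did not rank the libraries as Klf1 did (826, 1077 and 1086 CPM in WT 1 to 3, and 1439, 992 and 1089 CPM in cKO 1 to 3). A change in erythroid cells by genotype stays open as well.

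Several genes with small p-values were neighbours. On chromosome 1, Mcm6 (128331590 to 128359664), Dars and Ubxn4 had log2 fold changes of -1.62 ± 0.26, -0.38 ± 0.09 and -0.37 ± 0.09. R3hdm1, Rab3gap1 and Ccnt2, also within 1 Mb, had 0.24 ± 0.12, 0.16 ± 0.13 and 0.31 ± 0.14. Mgat5 (127205015 to 127488336), which starts outside that window and has an exon overlapping another gene, had -1.37 ± 0.28. Of the 100 genes with the smallest p, 17 lay on that chromosome, against a median of 6 in 10000 expression-matched draws (permutation p = 3.00e-04, for a chromosome picked after it was seen). Those 100 genes held 13 pairs within 1 Mb against a median of 8 in the draws (permutation p = 0.0763) and at most 11 in other splits; 6 of the pairs were among H2-Ab1, H2-Aa, H2-Eb1 and C4b, a cluster of immune genes, and 3 of the other 7 had opposite signs. Reads shared through overlapping exons are argued against, as in all 13 pairs the spans do not overlap. Multi-mapping reads shared by similar genes were not tested. A strain variant carried with the knocked-out allele was not seen within 10 Mb of Scin but is not excluded. There, 8.16% of 49 genes had an unadjusted p under 0.05, against a median of 6.12% in the draws (one-sided permutation p = 0.391). Segments of another strain elsewhere may differ between the groups, which the 13 pairs neither show nor exclude. The bounds first set read a p of 0.05 or more as against both strain explanations and needed a p under 0.05 against shared reads (it was 0.0716); they were not used, since a p that misses the threshold does not show an absence and genes whose spans do not overlap share no exon.

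Oxidative phosphorylation and actin regulator genes lay lower in cKO. A trend over transcript length and GC content is argued against as the whole cause, since with it removed the larger of the adjusted p-values was 6.77e-06 and the medians moved from -0.11 to -0.10 and from -0.12 to -0.13. Skeletal muscle in WT 2 is argued against too, since without WT 2 both lists passed (the larger adjusted p was 0.00158). Neither list passed with an estimated correlation, so a difference in the spread shared by their genes between these 6 libraries stays open, beside the genotype. A difference in cell types was not tested as a source and stays open too. Markers of fibroblasts, macrophages, adipocytes and endothelium lay lower (medians -0.33, -0.31, -1.12 and -0.43), and those of erythroid cells, neutrophils and osteoblasts higher. None of those marker lists passed with an estimated correlation either.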
